A study of Mus musculus with 8 samples.

How the data were processed

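Total RNA of dissected dorsal root ganglia with spinal cord was extracted with a spin-column kit and made into libraries with standard Illumina protocols, per the labels' protocols. The deposited files hold whole-number read counts per gene, 1 file per library. Per the submitters' processing notes, the tools named were FastQC 0.10.1, STAR 2.3.0e, SAMtools 0.1.18, featureCounts 1.4.6-p1 and DESeq2 1.8.2, with genome build mm10. Their settings, the annotation release, whether counting used strand and how reads shared by near-identical genes were counted are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart.

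Each file held 38355 genes with Ensembl identifiers and 5 summary rows, whose counts were 0 and which were left out. Symbols and coordinates came from GENCODE M21 (GRCm38, the same assembly as mm10), in which 36602 identifiers matched. The 1753 that did not match held 0.263% of counts. Library totals were 67782435, 27318883, 25490087 and 28500792 counts in WT replicates 1 to 4 and 27567399, 24690266, 26532920 and 23088908 in KO replicates 1 to 4. At the smallest total, 1 CPM is about 23 counts, so genes near 1 CPM rest on few reads. Mitochondrial genes held 0.0% of counts in each library, so this share cannot serve as a measure of RNA quality here. No 2 libraries of the same group agreed within sampling noise, which argues against repeat reads of the same library. That comparison cannot tell separate embryos from separate preparations of the same RNA. All 8 were counted as replicates. Groups were taken from the genotype in the sample labels.

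The KO and WT groups were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization (factors 0.991 to 1.012), robust quasi-likelihood fit and F test, a design with group alone, and Benjamini-Hochberg adjustment over 16068 genes at a threshold of 0.05. Log2 fold changes are KO over WT, and their SE was computed as the size of the log2 fold change divided by the square root of F. The biological coefficient of variation was 9.6%. CPM values use the TMM-adjusted library sizes, and list scores are means of log2 CPM with a prior count of 2.

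The 27 gene lists, the designs and the rule for named genes were fixed before the data were examined. The rule took Prdm12, and up to 12 largest rises and 12 largest falls among called genes. These needed a mean of at least 1 CPM in the higher group and no overlap between groups. Only 8 rises qualified, while more than 12 falls did and the 12 largest were taken. Up to 4 members of each list with the smallest p were also named by the rule. Other genes named in the text were chosen after their values were seen, among them Vsx1, Foxn4, Tal1, Bhlhe22, Sox10, Erbb3, Gm13425 and Ass1. Some genes that the rule named are not reported here. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 27 lists.

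On counts simulated from the real means and library sizes for KO against WT (15936 genes tested), the edgeR fit recovered 70% of 80 genes changed 1.5-fold, 89.7% of 58 changed 2-fold and 96.6% of 58 changed 4-fold, and 6.6% of its calls were genes simulated unchanged. In the same simulation 17.1% of DESeq2 calls and 5% of limma-voom calls were genes simulated unchanged, and camera called the shifted list of 15 genes and 0 of 20 unchanged lists. Each gene was simulated independently, with no difference between libraries other than group and depth. The simulation could therefore not show false list calls that come from correlation between members. Nor could it show false gene calls that come from other structure among the real libraries, so its rates need not hold for them.

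Alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a term, numeric covariates (a sex score from Y genes and Xist, a score of muscle and mesenchyme genes, a surrogate variable from sva 3.50.0), other list tests, and fits without each library or without 1 library of each group (16 fits). The surrogate variable correlated with the sex score at −0.96, so these covariates are not independent checks. A thinned WT replicate 1 and a stage score (mean log2 CPM of the cell cycle list) were added after the data were seen. Scores were compared by two-sided exact permutation tests over all assignments of 4 and 4 libraries, whose smallest p is 0.029. These p-values were not adjusted for the number of scores tested. After the data were seen, scores were also fitted in a linear model with group and the muscle and mesenchyme score. Calls near Prdm12 were tested with a two-sided Fisher exact test with a 95% interval. Figures were drawn with matplotlib 3.10.9.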

Results

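Gene expression was measured by RNA sequencing of total RNA from mouse embryos of the C57Bl6 strain at embryonic day E11.5. The tissue was dorsal root ganglia, the clusters of sensory neurons beside the spinal cord, taken at thoracic level together with the adjoining spinal cord. A group of 4 wild-type (WT) libraries was compared with a group of 4 libraries from embryos lacking Prdm12 (KO), a zinc-finger transcription factor of the PRDM family. The series text speaks of triplicates, whereas 4 libraries per group are listed and all 8 were used. The comparison addresses which genes depend on Prdm12 in somatosensory neurons. WT replicate 1 held 67782435 counts, 2.55 times the median of the other 7 libraries, which held between 23088908 and 28500792. The labels do not say whether libraries came from separate embryos or pools. The p-values weigh the group difference against the spread between these libraries, which need not equal the spread between embryos.

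Prdm12 itself (ENSMUSG00000079466, mm10 chromosome 2, 31640037 to 31655795, plus strand) was low in every KO library. It stood at 22.2, 37.9, 39.6 and 31.95 CPM (counts scaled to library size) in WT replicates 1 to 4 and at 1.55, 1.52, 0.975 and 0.962 CPM in KO replicates 1 to 4. The means were 32.9 ± 7.86 CPM (SD, n = 4) in WT and 1.25 ± 0.329 CPM (SD, n = 4) in KO. The log2 fold change was −4.70 (SE 0.24, adjusted p = 0.000124). The labels do not state which part of the gene was deleted, and Gm13425, an annotated gene that overlaps its start, had a log2 fold change of −1.53 without passing the test (adjusted p = 0.133).

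Among 16068 tested genes, 48 changed in KO, of which 39 fell and 9 rose. Apart from Prdm12 the deepest fall among genes above 1 CPM was in Cdhr1, which encodes a cadherin-related membrane protein. Cdhr1 (chromosome 14, 37077857 to 37098347) fell from 16.6 ± 5.94 to 2.91 ± 0.506 CPM (SD, n = 4 each; log2 fold change −2.50, SE 0.29, adjusted p = 0.00987). Among the other named falls, Slc17a7, which encodes the vesicular glutamate transporter VGLUT1, fell by 0.94 on the log2 scale, the potassium channel subunit gene Kcnmb2 by 0.93, and the metabotropic glutamate receptor gene Grm2 by 0.91. Rgs4, a regulator of G-protein signalling, fell by 0.90 on the same scale, Mreg by 0.83 and Wdr66 by 1.31. The long non-coding genes F730016J06Rik, 2610028E06Rik and Gm12688 had log2 fold changes of −1.62, −1.17 and −0.95. Gm12688 (chromosome 4, 99653607 to 99654983) lies 1316 bp from Foxd3, a transcription factor gene on the other strand that also fell (log2 fold change −0.57).

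**Figure D1:**
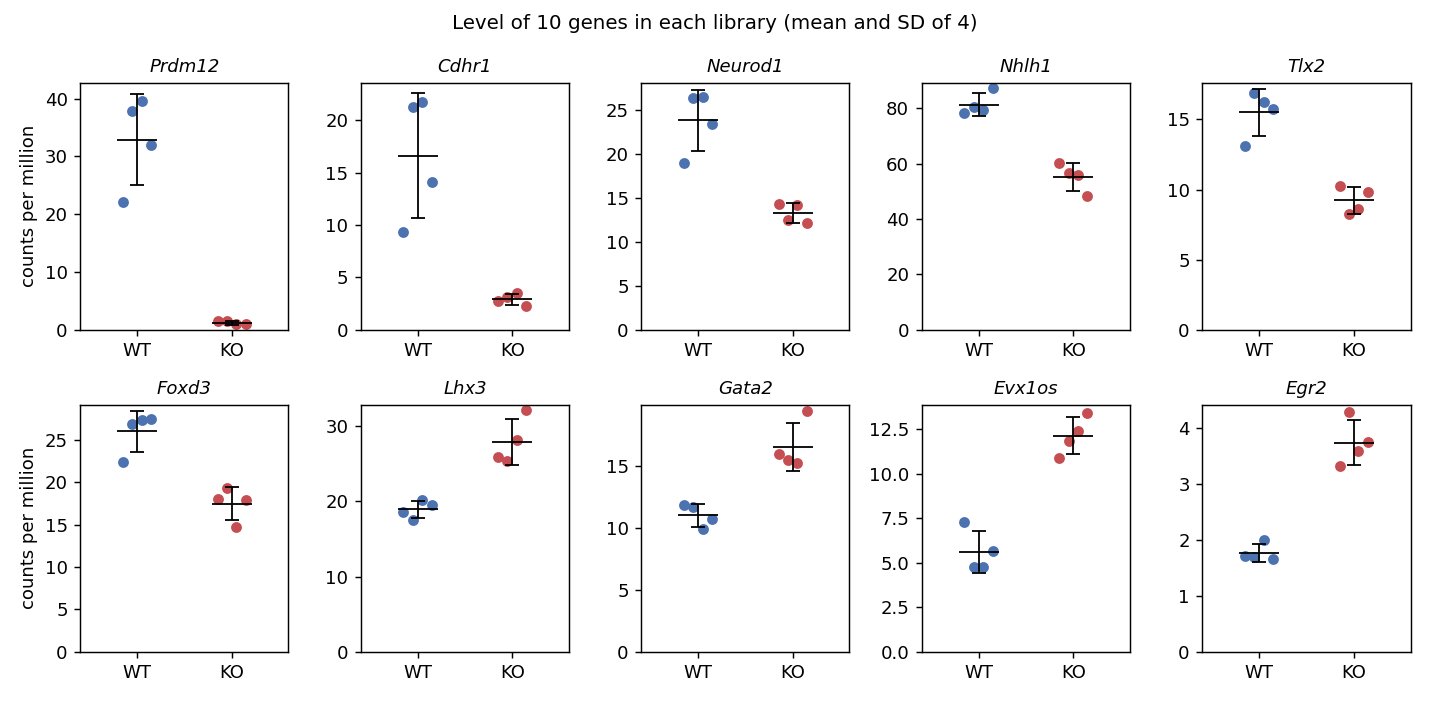
CPM of 10 genes in each library (vertical axes, starting at 0) for WT (blue) and KO (red); points are libraries, bars are the mean and SD of 4. Cdhr1 ranges from 2.32 to 3.49 CPM in KO and from 9.39 to 21.7 CPM in WT.

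The named rises included transcription factor genes of the V2 class of ventral spinal interneurons. Lhx3, a LIM homeobox gene, rose from 18.9 ± 1.14 to 27.9 ± 3.07 CPM (SD, n = 4 each; log2 fold change 0.56, SE 0.08, adjusted p = 0.0169). Sox14 rose by a log2 fold change of 0.82 and Gata2 by 0.58. Evx1os, annotated antisense to the homeobox gene Evx1 (chromosome 6, 52308389 to 52314832), rose from 5.61 ± 1.18 to 12.2 ± 1.05 CPM (SD, n = 4 each; log2 fold change 1.09, SE 0.14, adjusted p = 0.00778). The sources used here do not say whether counting was strand-specific, so reads of Evx1os and of Evx1, which it overlaps, cannot be told apart with certainty. Egr2, a zinc-finger transcription factor of Schwann cells and the hindbrain, rose from 1.77 ± 0.156 to 3.74 ± 0.404 CPM (SD, n = 4 each; log2 fold change 1.08, SE 0.13, adjusted p = 0.00673). The non-coding gene Gm26791 and C1ql4, which encodes a secreted protein of the C1q family, rose by 1.14 and 0.77 on the log2 scale.

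At least 2-fold changes were found in 4 of the rises and 9 of the falls. At an unadjusted p under 0.05 there were 487 higher and 533 lower genes, and the median log2 fold change of all tested genes was −0.003. Whichever single library was left out, 12 of the 48 genes stayed called, among them Prdm12, Kcnmb2, Grm2, Mreg, Nhlh1, Egr2, Evx1os, Jag1, Cldn12 and Gucy2c, the last 3 chosen after their values were seen. The other 36 lost the call in at least 1 such fit, Cdhr1 when any single KO library was left out, and Lhx3 without WT replicate 2, WT replicate 4 or KO replicate 3. Without WT replicate 1, 21 genes rose and 112 fell, the 48 among them, while leaving out any other library left between 3 and 5 rises and between 12 and 27 falls. With a numeric covariate for the muscle and mesenchyme genes described below, only Prdm12 passed (168 higher and 285 lower genes at an unadjusted p under 0.05), with the median log2 fold change of the 38 other lower genes at −0.72 against −0.74 and their median SE at 0.15 against 0.10.

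Lists of sensory lineage genes were called lower. The libraries hold spinal cord as well as ganglia, so a fall cannot be assigned to the ganglia alone. Of 14 sensory neurogenesis factors, 3 fell (Nhlh1, Neurod1 and Neurog1), none rose and 11 did not pass, and 7 fell when adjusted over the list alone. Neurod1, a basic helix-loop-helix factor of newborn neurons, fell from 23.8 ± 3.51 to 13.3 ± 1.12 CPM (SD, n = 4 each; log2 fold change −0.83), Nhlh1 had a log2 fold change of −0.55 and Neurog1, the factor that starts later sensory neurogenesis, −0.48. This list's call (camera adjusted p = 2e-19) lay at the threshold with an estimated correlation (adjusted p = 0.047). It was lost there with library totals (adjusted p = 0.058), with a stricter filter, 1 surrogate variable or WT replicate 1 thinned (adjusted p = 0.052 for each), and with the stage score (0.063), the sex score (0.09), the muscle and mesenchyme score (0.20) or a replicate block (0.23). It was also lost, at an adjusted p between 0.09 and 0.13, without WT replicate 2, 3 or 4 or KO replicate 2, 3 or 4. Of 15 tested general sensory identity genes, 3 fell, namely Tlx2 (−0.74), Pou4f1, which encodes Brn3a (−0.52), and Eya2 (−0.39), and 7 fell when adjusted over the list alone. Its call (adjusted p = 1.8e-15) was lost with an estimated correlation (adjusted p = 0.11). Nefm, a neurofilament gene, had 1028 ± 82.2 CPM in WT and 842 ± 25.3 CPM in KO (SD, n = 4 each) and missed the threshold (adjusted p = 0.0916).

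The nociceptor lineage list was also called lower (adjusted p = 9.9e-10, and adjusted p = 0.12 with an estimated correlation). Of its 11 tested members 1 fell and 10 did not pass. Adjusted over the list alone, 3 fell, among them the sodium channel gene Scn10a (log2 fold change −1.77) and the ATP-gated channel gene P2rx3 (−0.61). Scn10a stood at 2.70 ± 1.23 CPM in WT and 0.756 ± 0.315 CPM in KO (SD, n = 4 each). The mechanoreceptor and proprioceptor list was not called (adjusted p = 0.24), with 0 of 11 tested members passing. Its member with the smallest p, Runx3, a factor of proprioceptors, had 15.1 ± 4.80 CPM in WT and 6.84 ± 2.36 CPM in KO (SD, n = 4 each; log2 fold change −1.13, adjusted p = 0.501). This list was called lower with limma-voom (adjusted p = 0.025), 1 surrogate variable (adjusted p = 0.021, and adjusted p = 0.48 with an estimated correlation) and the stage score as covariate (adjusted p = 0.00014, and adjusted p = 0.16 with an estimated correlation), each with 1 member falling. It was also called lower without WT replicate 1 (adjusted p = 8.6e-05, and adjusted p = 0.36 with an estimated correlation) and without KO replicate 2 (adjusted p = 0.009, and adjusted p = 0.70 with an estimated correlation). WT replicate 1 stood apart within its group, with Scn10a at 0.966 CPM against 2.68 to 3.65 CPM in the other WT libraries. Without that WT library the nociceptor and sensory identity calls held with an estimated correlation (adjusted p = 0.0083 and 0.0046), as the nociceptor call also did with the stage score as covariate (adjusted p = 0.026).

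In the spinal cord, lists of neighbouring ventral interneuron classes were called in opposite directions. The V2 list rose (adjusted p = 3.4e-20, and adjusted p = 0.0015 with an estimated correlation), with 4 of 11 members rising, 0 falling and 7 not passing. With an estimated correlation it held with the muscle and mesenchyme score as a covariate (adjusted p = 0.0065) but not with a replicate block (adjusted p = 0.054). Adjusted over the list alone, 8 rose, among them Vsx1, Foxn4, Gata3 and Tal1 at log2 fold changes of 0.91, 0.74, 0.52 and 0.31, and 1 fell (Bhlhe22, −0.19). The V0 list was called higher (adjusted p = 1.6e-07, and adjusted p = 0.14 with an estimated correlation) although 0 of its 6 members passed over all genes. Adjusted over the list alone, 4 rose, among them Evx1 (0.85), Evx2 (0.74) and the p0 progenitor gene Dbx1 (0.25). The V1 list was called lower (adjusted p = 0.0021, and adjusted p = 0.33 with an estimated correlation), with a median of −0.11 that was −0.06 without WT replicate 4 or without KO replicate 3. Of its 10 members Foxd3 fell, from 26.0 ± 2.44 to 17.5 ± 1.93 CPM (SD, n = 4 each), and 9 did not pass. Foxd3 is also a neural crest gene and is in both lists. En1, the homeobox gene that defines V1 neurons, had a log2 fold change of −0.54 and fell when adjusted over the list alone (adjusted p = 0.0228), but not over all genes (adjusted p = 0.393).

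**Figure D2:**
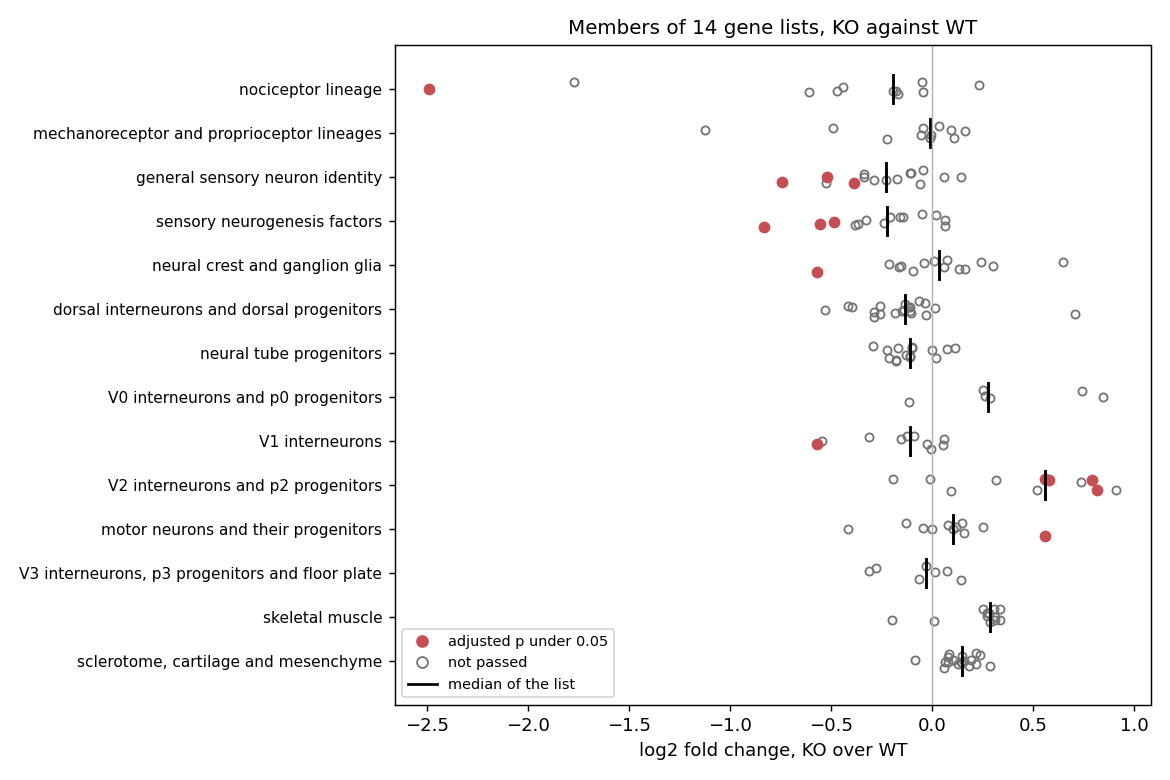
Log2 fold change in KO over WT (horizontal axis) of every tested member of 14 gene lists fixed before the data were examined; red points passed at an adjusted p under 0.05, open points did not, and black bars are list medians. The medians lie at 0.56 for V2, 0.28 for V0 and −0.11 for V1 genes, and at −0.22 and −0.23 for the sensory neurogenesis and sensory identity lists.

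**Figure D3:**
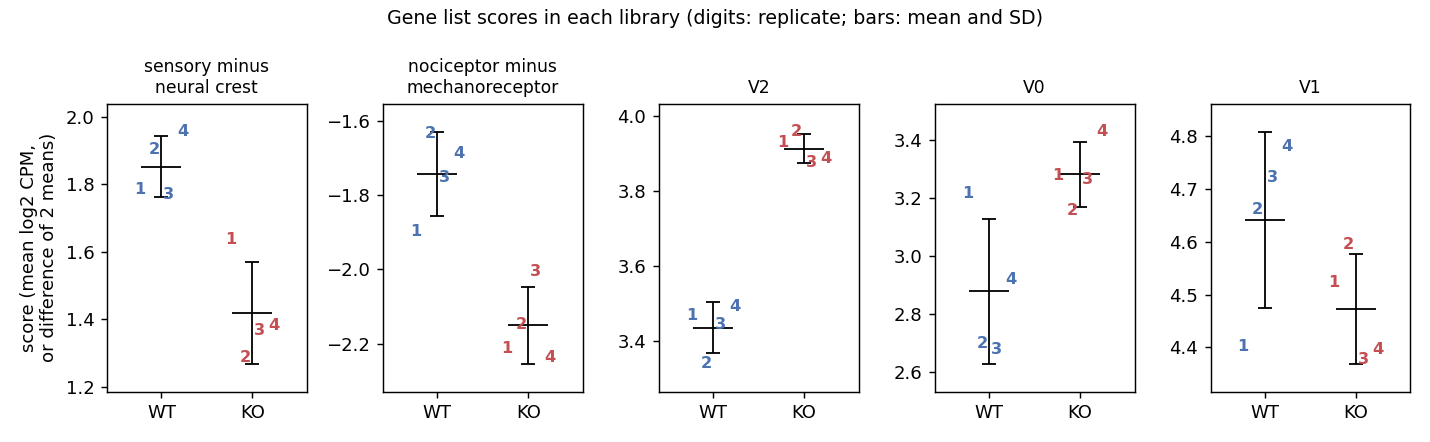
Scores of gene lists (vertical axes, mean log2 CPM of the members, or the difference of the means of 2 lists) in each library for WT (blue) and KO (red); digits are replicate numbers and bars the mean and SD of 4. The V2 score lies between 3.88 and 3.96 in KO and between 3.34 and 3.49 in WT, whereas for the V1 score WT replicate 1, at 4.40, lies among the KO libraries, which range from 4.38 to 4.59.

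The motor neuron list was called higher (adjusted p = 0.041, and adjusted p = 0.36 with an estimated correlation) with 1 of 11 tested members rising, Lhx3, which the V2 list also holds. That call was lost without WT replicate 1 (adjusted p = 0.17), WT replicate 2 (adjusted p = 0.091) or KO replicate 4 (adjusted p = 0.31), and with limma-voom (adjusted p = 0.28), no filter on low counts (adjusted p = 0.072) or the muscle and mesenchyme score as covariate (adjusted p = 0.95, tested as lower). Isl2, a motor and sensory neuron factor, had a log2 fold change of −0.42 (adjusted p = 0.0916). Dorsal interneuron genes and neural tube progenitor genes were called lower with medians of −0.14 and −0.11 (adjusted p = 0.0019 and 0.0012), each lost with an estimated correlation (adjusted p = 0.33 for each), and 0 of their 20 and 15 members passed. Both calls were also lost with limma-voom (adjusted p = 0.10 and 0.22) and with the muscle and mesenchyme score as covariate (adjusted p = 0.19 and 0.26, each tested as higher), and the progenitor call without WT replicate 1 (adjusted p = 0.16). The medians were −0.08 and −0.06 without WT replicate 1 and −0.21 and −0.16 without KO replicate 1. The list of V3 interneurons and floor plate was not called (adjusted p = 0.65), though it was called lower with the muscle and mesenchyme score as covariate (adjusted p = 0.013, and adjusted p = 0.32 with an estimated correlation).

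Lists of tissue around the neural tube were called higher in KO, beside the lower sensory lists and the higher V2 list. The skeletal muscle list had a median log2 fold change of 0.28 (adjusted p = 9.9e-10, and adjusted p = 0.16 with an estimated correlation), and the list of sclerotome, cartilage and mesenchyme a median of 0.15 (adjusted p = 6.5e-06, and adjusted p = 0.14 with an estimated correlation). Without KO replicate 4 the muscle median was 0.17, and without WT replicate 1 the mesenchyme median was 0.10, each list still called higher (adjusted p = 4.7e-06 and 0.00067, and adjusted p = 0.26 and 0.30 with an estimated correlation). None of their 12 and 18 members passed over all genes, and adjusted over the list alone 3 muscle genes rose (Myod1, Myl4 and Des). Myod1, the myogenic factor, stood at 42.1 ± 4.20 CPM in WT and 53.1 ± 7.82 CPM in KO (SD, n = 4 each). The mean log2 CPM over the 2 lists was 6.16, 6.30, 6.27 and 6.17 in WT replicates 1 to 4 and 6.28, 6.40, 6.40 and 6.53 in KO replicates 1 to 4.

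The neural crest and ganglion glia list was not called (adjusted p = 0.93), with Foxd3 falling and 13 members not passing. Adjusted over the list alone, 1 member rose and 1 fell. Sox10 and Erbb3, markers of crest-derived glia, had log2 fold changes of 0.16 and 0.13 and did not pass. The visceral sensory and autonomic list was not called (adjusted p = 0.41). No member of the cell cycle list (adjusted p = 0.41), the p53 target list (adjusted p = 0.54) or the list of other PRDM genes (adjusted p = 0.95) passed. The lists of Hox genes anterior to the thorax (adjusted p = 0.91), thoracic Hox genes (adjusted p = 0.29), and lumbar and sacral Hox genes (adjusted p = 0.54) were not called. Lists for erythroid cells (adjusted p = 0.41), endothelium (adjusted p = 0.95), macrophages (adjusted p = 0.16), surface epithelium (adjusted p = 0.95), sex-linked genes (adjusted p = 0.95) and immediate early genes (adjusted p = 0.78) were not called, with Egr2 the called member of the last. Leaving out WT replicate 1 gave calls for the thoracic Hox list (lower, adjusted p = 4e-05) and the anterior Hox list (higher, adjusted p = 0.002), and leaving out other single libraries gave calls for the thoracic Hox (without KO replicate 2, adjusted p = 0.022), lumbar and sacral Hox (without KO replicate 1, adjusted p = 0.039), cell cycle (without KO replicate 3, adjusted p = 0.046), erythroid (without KO replicate 3, adjusted p = 3.9e-07) and macrophage lists (without WT replicate 3 or KO replicate 4, adjusted p = 0.019 and 0.031). With all 8 libraries, limma-voom called the anterior Hox list higher (adjusted p = 0.0068) and the thoracic Hox list lower (adjusted p = 0.0098), and the stage score as covariate called the thoracic Hox list lower (adjusted p = 0.0068). The muscle and mesenchyme score as covariate gave calls for the anterior Hox list (higher, adjusted p = 6.9e-06), the lumbar and sacral Hox list (higher, adjusted p = 0.00057) and the endothelium list (lower, adjusted p = 5.6e-05). With an estimated correlation, which was not run with limma-voom, none of these calls held, and the adjusted p lay between 0.18 and 0.89. The median and the direction of the test differed in sign for immediate early genes (median −0.01) and anterior Hox genes (median −0.02), each tested as higher, and the mean differed from the test for lumbar and sacral Hox genes (mean 0.26, tested as lower) and sex-linked genes (mean −0.04, tested as higher).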

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

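The tests of calls along chromosome 2 beyond Prdm12, of the odds without Lhx3, of the V0 plus V2 score minus the V1 score, of the stage score, of list scores across the other split and of scores with the muscle and mesenchyme covariate were chosen after the results were seen, the other tests before.

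Lower sensory neuron genes in KO. The score of sensory identity genes minus that of 6 crest and glial genes differed in KO by −0.43 log2 units (two-sided exact permutation p = 0.029, the smallest these libraries allow). It was lower in 4 of 4 KO libraries than in any WT library. The part of the 6 crest genes was itself higher by 0.20 (exact permutation p = 0.171), by 0.12 without WT replicate 1 and by 0.13 without KO replicate 2. The score of the whole list of 14 crest and glial genes differed by only 0.019, with 8 members higher and 6 lower. As the crest genes did not fall as a set, this argues against less ganglion tissue in the KO dissections as the whole cause. With the muscle and mesenchyme score as covariate the sensory minus crest difference was −0.31 (SE 0.132), within a 95% bound of 0.338. The values therefore do not argue against less ganglion together with more surrounding tissue. The nociceptor minus mechanoreceptor score differed by −0.41 (exact permutation p = 0.029). The libraries also hold spinal cord, and the mechanoreceptor and proprioceptor list shares Shox2 with the V2 list. Reads from other cells could dilute the fall of that list, so the score cannot decide on an equal loss of every sensory type. The list was itself called lower with limma-voom, 1 surrogate variable or the stage score (adjusted p = 0.025, 0.021 and 0.00014). With an estimated correlation, not run with limma-voom, the adjusted p was 0.48 and 0.16 for the last 2. An earlier stage of the KO embryos stays open: the stage score differed between groups by only −0.028 (SD 0.114 in WT and 0.115 in KO), so as a covariate it could not move the median log2 fold change of the 38 lower genes other than Prdm12 (−0.744 against −0.74). With the same muscle and mesenchyme covariate that median was −0.719 with all 38 still below 0. Of these genes 0 stayed called, as the median SE of single genes rose from 0.10 to 0.152. The sensory identity score differed by −0.27 (SE 0.185) against −0.24 (SE 0.11), a move smaller than its SE. The wider spread leaves surrounding tissue open. The neurogenesis score shrank from −0.26 (SE 0.078) to −0.16 (SE 0.118), while the nociceptor score grew from −0.55 (SE 0.202) to −0.64 (SE 0.337). Both lay within their 95% bounds (0.303 and 0.867). As a hypothesis beside these, loss of Prdm12 may lower nociceptor genes more than mechanoreceptor and proprioceptor genes. The nociceptor minus mechanoreceptor score cannot decide it, and was not fitted with the muscle and mesenchyme covariate.

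Higher V0 and V2 genes with lower V1 genes in KO. A larger ventral share of spinal cord was first tested on the V1 score alone, which differed by −0.17 against an SD of 0.167 in WT (exact permutation p = 0.114) and decided nothing; after both values were seen it was replaced by the V0 plus V2 score minus the V1 score. That was higher in KO by 0.62 log2 units (exact permutation p = 0.029), whereas a larger ventral share would raise all of them together, so the values argue against it only in a test picked with its result known. The V0 plus V2 score minus the motor neuron plus V3 score was higher in KO by 0.46 (exact permutation p = 0.029), which argues against a change across all ventral populations. With the muscle and mesenchyme score as covariate the V2 score was higher in KO by 0.54 (SE 0.052, against 0.48 without it) and the V0 plus V2 score minus the V1 score by 0.69 (SE 0.231, 95% bound 0.593, against 0.62 without it), which argues against surrounding tissue as the whole cause of either. Taken singly, the V0 and V1 scores differed by 0.51 (SE 0.223) and −0.16 (SE 0.166) against 0.40 (SE 0.137) and −0.17 (SE 0.098) without it, and both lists kept their call at the preset correlation (adjusted p = 2.7e-08 and 0.023) but not at an estimated one (adjusted p = 0.18 and 0.57, and 0.14 and 0.33 without the covariate); the spread of each leaves surrounding tissue open for that list alone.

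Calls near Prdm12. Within 10 Mb of Prdm12, 3 of 264 tested genes were called (Lhx3, F730016J06Rik and Ass1, the last 119365 bp away with a log2 fold change of −0.80), against 44 of 15645 elsewhere (odds ratio 4.07, 95% interval 0.8 to 12.84, Fisher exact p = 0.0429), as flanking DNA of another strain could give. The excess was also present on chromosome 2 beyond 20 Mb of Prdm12 (8 of 992 genes, odds ratio 3.1, 95% interval 1.25 to 6.76, Fisher exact p = 0.00796), where it included Neurod1 and Eya2. Without Lhx3, a member of the V2 list, the odds ratio within 10 Mb was 2.72 (95% interval 0.32 to 10.51, Fisher exact p = 0.176). Strain-specific DNA was not tested directly.

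The count of 48 called genes was reached by 2 of the 35 splits of the 8 libraries into 4 and 4, the real split included, so chance is not excluded by this count. The other split, WT replicate 1 with KO replicates 1, 3 and 4 against the rest, called 194 genes, of which 0 were among the 48. A split with several times the real count points to a structure of the samples. Scores of 8 of the 27 lists part these libraries without overlap, so they do not single out 1 cause. Those of the cell cycle (the stage score, 7.43 to 7.62 against 7.26 to 7.42), anterior Hox (5.71 to 6.01 against 5.57 to 5.70) and V0 lists are higher with WT replicate 1. Those of the thoracic Hox (6.07 to 6.47 against 6.49 to 6.69), nociceptor, mechanoreceptor and proprioceptor, neural crest and V1 lists are lower. With the stage score as covariate 27 genes rose and 145 fell, the 48 among them; position along the trunk was not used as a covariate.

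Far single libraries were found in 14 of 152 group values tested, where about 7.6 would come by chance; each value below is the gap to the nearest library over the whole range. WT replicate 1 was far from the other WT libraries in its total (0.929), in the lower level of Ppp1r14a (0.929), Foxd3 (0.873) and Syt13 (0.841), and in lower scores of the nociceptor (0.879), mechanoreceptor and proprioceptor (0.842) and general sensory (0.902) lists. WT replicate 2 was low for Grm2 (0.909). KO replicate 2 was low for Wdr66 (0.851), KO replicate 4 was high for 2610028E06Rik (0.852) and low for Pou4f1 (0.915), and KO replicate 1 was high for Cntn2 (0.881). The motor neuron score was high in KO replicate 4 (0.834) and the neural tube progenitor score in KO replicate 1 (0.871).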

How the results depend on the processing

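The stage score and the thinning of WT replicate 1 were chosen after the data were seen. The Prdm12 log2 fold change stayed called in every setting run and lay between −4.975 and −4.483. The 9 rises and 39 falls became 22 and 81 with DESeq2, 20 and 95 with limma-voom, 21 and 82 with 1 surrogate variable, 27 and 145 with the stage score, 0 and 1 with the muscle and mesenchyme score, and 4 and 9 at a fold of at least 2. Other scalings, filters, the sex score and thinning gave 8 to 13 rises and 34 to 58 falls. Leaving out libraries, singly or 1 per group, gave 0 to 30 rises and 1 to 252 falls, the highest counts being without WT replicate 1 and KO replicate 2; with WT replicate 1 kept, fits of 3 against 3 gave 0 or 1 rises and 1 to 7 falls. Same-numbered libraries did not pair: their deviations correlated at −0.11, 0.28, −0.19 and −0.01, and 1 of 8 libraries correlated best with its own number; a replicate block left 2 rises and 14 falls. Lists called fell from 11 to 2 with an estimated correlation and to 2 with fry, and were 8 to 15 with libraries left out. With the muscle and mesenchyme score as covariate, list medians were −0.055 for motor neurons, 0.094 for dorsal interneurons, 0.028 for neural tube progenitors, 1.532 for lumbar and sacral Hox genes, −0.141 for endothelium and −0.043 for skeletal muscle, each with the opposite direction of its main test; the skeletal muscle genes are part of that score, and the cause was not tested for the others. With libraries left out, the median of surface epithelium ranged from −0.33 to 0.345 and that of the cell cycle list from −0.074 to 0.086, with called rises, against the direction of the main test, only without WT replicate 1 and KO replicate 1 or 2 for the first and without WT replicate 1 and KO replicate 2 for the other. The odds ratio near Prdm12 was 4.45 within 5 Mb and 3.31 within 20 Mb (Fisher exact p = 0.0801 and 0.0699), no longer past the threshold; the cause was not tested. Outside the fits with libraries left out, 1534 of 1674 values of named and called genes kept their side of the threshold. Another 92 lost the call, 48 gained it and 0 changed direction as called genes. With libraries left out, 2543 of 3340 values kept their side and 753 lost the call. These totals include list members not called in the main fit, which kept their side by staying uncalled. All losses fell on the 48 called genes, so the shares kept understate how often calls were lost. Of the 48, 36 lost the call in at least 1 fit without a single library. Depth limits genes near 1 CPM most, at 23088908 counts in KO replicate 4.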

Other observations

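The boundary cap genes were listed after the rise of Egr2 and the levels of crest genes were seen, and the tests on them were set before their score was seen. Krt87, a keratin gene, rose from 0.314 ± 0.0226 to 0.796 ± 0.103 CPM, and Gucy2c, a guanylate cyclase receptor gene, fell from 0.731 ± 0.193 to 0.0403 ± 0.0359 CPM (SD, n = 4 each); both were below the 1 CPM of the rule for named genes and were chosen after their values were seen. Other falls chosen in the same way were those of Jag1, a Notch ligand, at a log2 fold change of −0.50, Cntn2, an axonal adhesion molecule, at −0.44, Cldn12 at −0.36 and Cadm1 at −0.28. The synaptotagmin genes Syt13 and Syt2 had log2 fold changes of −0.60 and −0.53.

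Lumbar and sacral Hox genes varied between libraries far more than between groups. Hoxc10 ranged from 16.2 to 70.2 CPM in WT and from 6.995 to 59.7 CPM in KO, and Hoxd10 from 0.906 to 21.8 CPM in WT and from 0.113 to 14.7 CPM in KO. Y-linked genes were present in WT replicates 2 and 3 and KO replicates 1 and 2, with Eif2s3y at 36.6 to 53.7 CPM against at most 0.119 CPM in the others, so that each group held 2 such libraries. The edgeR interaction of genotype with the sex score called 0 genes, with 438 of 16068 at an unadjusted p under 0.05.

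Egr2 marks boundary cap cells, crest-derived cells at the points where nerve roots meet the spinal cord. A hypothesis that the KO libraries may hold more of them was tested on 6 other boundary cap genes (Prss56, Wif1, Hey2, Npr3, Ntn5 and Sema6a). Their score was higher in KO by 0.15 log2 units (exact permutation p = 0.086), and by 0.07 without WT replicate 1, so the spread between libraries leaves the question open. None of the 6 passed, and the largest log2 fold change was 0.47 for Prss56 (adjusted p = 0.77).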
